A study of Homo sapiens with 4 samples.

How the data were processed

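Per the labels' protocols, biotin-labelled material made from total RNA of U87 cells was hybridised to 4 Affymetrix arrays. There was 1 array for each of 4 groups (DMSO control, ONC201, ONC206 and ONC212), each treated for 72 hours in medium with 1.5% serum. The authors deposited 1 table of log2 expression values with 23786 probe sets and 4 arrays. Per the submitters' processing notes the values were made with RMA, R 2.15.1 and the affy package 1.36.1. RMA corrects the background, gives all arrays 1 distribution of probe signals and combines the probes of a set into 1 log2 value. That step assumes that the overall distribution of RNA levels is alike in all groups, and it compresses changes of dim genes. The probe set definitions, any filter and a detection call are not given in the sources used here. The columns ran from 0.376 to 12.3, with medians between 3.55 and 3.61.

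Each probe set was named from the platform annotation given with the series. Of all probe sets, 22458 had 1 gene, 0 had several and 1328 were unnamed here, and no gene had more than 1 probe set. The reference table's assembly is not tied to the array, so no coordinates are printed and the table served for biotypes, older symbols and overlapping genes. A gene was kept where its highest value on the 4 arrays reached the median of all gene values, 3.64, which left 11958 genes. The number of arrays limits the precision. With 1 array per group there is no replicate error, and no p-value was computed. The control and ONC201 columns were not identical (r = 0.991 across genes).

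Differences were taken on the deposited log2 scale for each compound against control and for each pair of compounds, 6 comparisons in all, and genes at least 2-fold apart were counted. For each of 38 gene lists fixed before the data were examined, the median difference over its kept genes was set against 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these arrays and is not a p-value. The 95% interval of a list median comes from the ranks of its genes. Lists with under 5 kept genes (dopamine receptors and signalling, endothelial, immune and epithelial markers, and mitochondrially encoded genes) got no median. Of 60 cytosolic ribosomal protein genes 38 were named on the array. Because 3 comparisons share the control array, correlations between them were set beside simulated unchanged arrays, with noise taken from the ONC201 and control difference, and differences from pairs of arrays that share none were also correlated.

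Genes named in the text are the 10 highest and 10 lowest of each comparison, up to 2 members at either end of a list, 12 genes fixed in advance and the 10 genes at either end of the differences that share no array. This rule and the settings were fixed before the data were examined. For 2 comparisons the text names part of the genes this rule gives. GDF15 (for its overlap), GAS5, ZFAS1, SNHG12 and SNHG3 are named outside it, after their values were seen.

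The alternatives were no filter on dim genes, a stricter filter (mean of the 4 arrays at or above the 60th percentile, 4.77), centring of each array on the median of its kept genes, cyclic loess normalization (limma 3.58.1 in R 4.3.3), a 1.5-fold threshold, list means in place of medians, and correlations without the 100 most variable genes. Averaging several probe sets of a gene was planned and could not differ, since each gene had 1. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The counts and percentiles were tested on simulated data for ONC212 against control over 11958 genes. Genes changed by 0.8 on the log2 scale were called at 2-fold in 8% of cases, those changed by 1.2 on the log2 scale in 92%, those changed by 2 in 100%, and 16 unchanged genes were called. Of 40 unchanged lists, 3 fell outside the central 95% of random lists. The simulated noise was normal, independent between genes and scaled to the robust spread of the ONC201 and control difference. That real pair had 51 genes at least 2-fold apart, and differences between cultures were not simulated. These figures therefore check the method and are not the error of the arrays.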

Results

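Genome-wide mRNA levels were measured in U87, an established human glioblastoma cell line, after 72 hours with 200 nM ONC201, ONC206 or ONC212, or with the 0.1% DMSO vehicle alone. The series title describes ONC206 and ONC212 as derivatives of ONC201, and the design asks what each compound did to the transcriptome of glioma cells at 1 dose and 1 time. Each of the 4 groups was represented by 1 array. No value below therefore has a replicate error, no test between groups was possible, and every difference describes these arrays rather than the treatments in general. Levels are log2 expression values, a difference of 1 is 2-fold, and list medians carry a 95% interval over the list's genes, which is not a replicate error. Of 22458 named genes, 11958 passed the filter on dim genes. The robust SD of the difference between the ONC201 and control arrays, the closest pair (Pearson r = 0.991 across genes), was 0.39 in the dimmest of 20 level bins and 0.09 in the brightest. This spread contains any effect of ONC201 and was used as the yardstick for the other differences.

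Stress response and proliferation genes fixed in advance differed from control by small amounts with ONC201, by more with ONC206 and by most with ONC212, while CCND1, CLPP, DRD2 and TNFSF10 did not follow this order. ASNS, which makes asparagine and is a textbook ATF4 target, was at 6.07 in control, 6.39 with ONC201, 8.72 with ONC206 and 9.17 with ONC212. CHAC1, a glutathione-degrading enzyme induced by the same transcription factor, read 6.17, 6.20, 8.86 and 9.36 in that order. The pseudokinase gene TRIB3 was 3.07-fold higher than control with ONC206 and 4.47-fold higher with ONC212. ATF4 itself was 1.99-fold and 2.45-fold higher, and DDIT3, which encodes the stress factor CHOP, was 1.60-fold and 2.86-fold higher. TNFRSF10B, the TRAIL receptor DR5, stood at 7.39 in control, 7.58 with ONC201, 7.95 with ONC206 and 8.82 with ONC212. CDKN1A, the cell cycle inhibitor p21, was 1.23-fold higher than control with ONC206 and 1.89-fold higher with ONC212. With ONC201, ATF4 (-0.16), DDIT3 (-0.12), TRIB3 (-0.11) and CDKN1A (-0.06) were slightly below control, while ASNS, CHAC1 and TNFRSF10B were slightly above. The proliferation marker MKI67 went the other way, from 9.42 in control and 9.39 with ONC201 to 7.69 with ONC206 and 4.14 with ONC212. CCND1, which encodes cyclin D1, differed from control by no more than 0.13 with any compound. CLPP, the mitochondrial protease that these compounds are known to activate, lay between 7.18 and 7.33 on all 4 arrays. DRD2, a dopamine receptor also described as a target of ONC201, and TNFSF10, which encodes TRAIL, did not pass the filter, with levels no higher than 2.79 and 2.01.

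**Figure D1:**
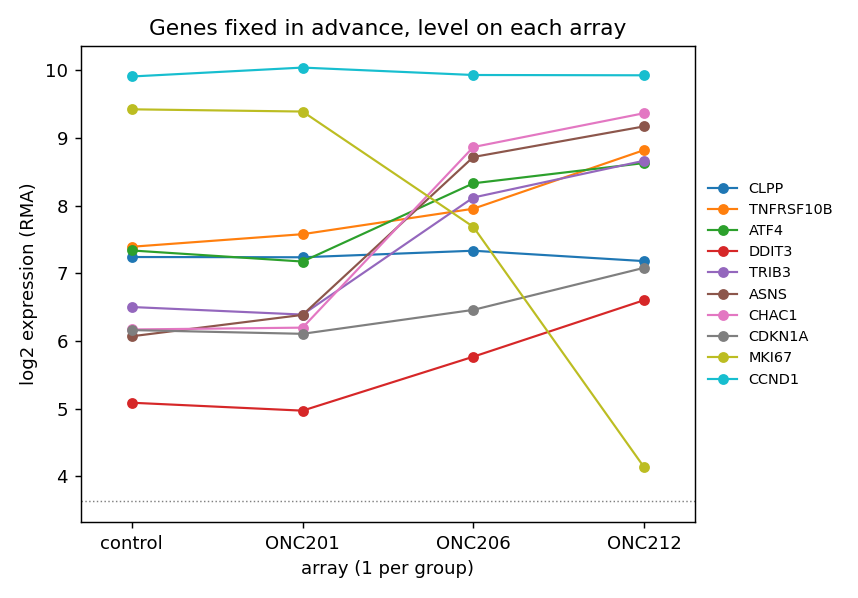
Log2 expression (RMA, y axis) of 10 genes fixed in advance on each of the 4 arrays (x axis, 1 array per group). Points are single arrays, lines join the values of 1 gene, and the dotted line is the filter level of 3.64; ASNS and CHAC1 are higher and MKI67 is lower with ONC206 and ONC212, while CLPP and CCND1 stay near their control level.

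The first comparison asked what ONC201 did at this dose. With ONC201, 30 genes were at least 2-fold higher and 21 at least 2-fold lower than in control, 0.426% of the genes kept. They were dim, with a median level of 3.50 against 6.09 for all genes kept, and 62.7% of them were protein-coding genes against 90.9% overall. The 10 highest included CDY2B (+2.0), a multi-copy Y-linked gene family member, the immunoglobulin and T cell receptor segments IGKV3-11 (+1.38), IGHV3-15 (+1.28) and TRBV7-3 (+1.49), and the small RNAs MIR194-2 (+1.40) and SNAR-D (+1.31). MTHFS (+1.53), CCNYL2 (+1.35), TAS2R14 (+1.26) and ANXA8L1 (+1.23) completed them. The lowest was RANBP3L (-2.04), followed by MIR4469 (-1.43), OVCA2 (-1.37), EIF4EBP3 (-1.31), LINC01119 (-1.30), TTC34 (-1.27), ITGA10 (-1.27), STEAP1 (-1.22), SNORA11 (-1.20) and CMC1 (-1.19). OVCA2, MIR4469, SNORA11 and CMC1 overlap another gene of the array in the reference annotation, and probes of multi-copy families cannot separate their members. Under a stricter filter on dim genes, 1 gene was higher and 3 were lower.

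No fixed stress or cell cycle list differed with ONC201 by more than a small amount. The 29 measured integrated stress response genes had a median difference of 0.03 (95% interval over genes -0.06 to 0.15), with 0 genes at least 2-fold from control. The 57 mitosis genes had a median of -0.03 (-0.06 to 0.03) and the 46 DNA replication genes one of -0.01 (-0.07 to 0.04). The largest list shift was in hypoxia targets, with a median of 0.30 (0.16 to 0.36) that lay above all 10000 random lists matched on expression. Of its 22 genes, 21 were above control, including INSIG2 (+0.48) and PDK1 (+0.45), a kinase that holds back pyruvate oxidation. Glycolysis genes were also above all 10000 random lists, with a median of 0.14 (0.07 to 0.29) and 0 of 20 genes at 2-fold. HK2, the first enzyme of glycolysis, was at +0.56 and the glucose transporter SLC2A3 at +0.53. Nuclear-encoded subunits of respiratory complex I (median -0.09, -0.13 to -0.01; percentile 0.715) and of complexes II to V (median -0.09, -0.20 to -0.03; percentile 0.48) lay slightly below matched lists, as did mitochondrial DNA maintenance genes (median -0.15, -0.29 to 0.10; percentile 2.08). FOXO targets (median 0.11, -0.18 to 0.17; percentile 99.3) and p53 targets (median 0.05, -0.04 to 0.09; percentile 97.8) lay slightly above. The intervals of the last 3 lists include 0, and 9 FOXO targets were above control and 6 below. These are the 7 of 33 lists outside the central 95% of random lists, where 1.65 would be for random picks of genes. Genes of a fixed list may vary together between cultures, so with 1 culture per group this excess is not read as an effect of ONC201.

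ONC206 was higher than control by at least 2-fold for 121 genes and lower for 248. The highest were UNC5B (+2.84), a netrin receptor, CHAC1 (+2.69), CBS (+2.68), which makes cystathionine, LINC02806 (+2.66), ASNS (+2.65), CADM1 (+2.27), the complement receptor C5AR1 (+2.25), the kinase RPS6KA2 (+2.24), PAPPA2 (+2.18) and ALDH1L2 (+2.11), a mitochondrial folate enzyme. The lowest were RANBP3L (-3.00), CXADR (-2.78), which encodes the coxsackievirus and adenovirus receptor, CDCA3 (-2.22), SKA3 (-2.03), RTKN2 (-2.01), ITGA10 (-2.01), the histone gene H2BC6 (-2.0), RGS4 (-1.98), the mitotic kinase PBK (-1.95) and PDK4 (-1.90). On the ONC206 array RANBP3L (2.31), CXADR (2.52), ITGA10 (2.46), H2BC6 (2.68) and PDK4 (2.25) lay under the filter level. Their differences and ranks therefore depend on the lower end of the array's range. RANBP3L and ITGA10 were also among the lowest with ONC201 (-2.04 and -1.27). Both comparisons use the same control array, and its share in these differences was not separated. CXADR, CDCA3, PBK, RPS6KA2 and UNC5B overlap another gene on the array in the annotation. When each array was centred on its own median, 162 genes were higher and 210 lower, which moved the higher share from 32.8% to 43.5%.

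The genes higher with ONC206 included much of the amino acid stress programme. Of the 29 measured ATF4 and integrated stress response targets, 17 were at least 2-fold higher, 12 were within 2-fold and 0 were lower. Their median was 1.22 (0.81 to 1.60), above all 10000 random lists. Next to CHAC1, CBS and ASNS, the amino acid transporter SLC7A5 was 2-fold higher or more, and SLC7A1 (+0.20) and PPP1R15A (+0.09) were the least different. Of 13 genes for serine, one-carbon and proline synthesis, 4 were at least 2-fold higher, with a median of 0.61 (-0.33 to 1.57). ALDH1L2 and PSAT1 (+2.01), the second enzyme of serine synthesis, led this list, and SHMT1 (-0.97) and PYCR3 (-0.70) were its lowest. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a median of 0.66 (0.08 to 1.06), with 5 of 19 at 2-fold or more, led by WARS1 (+1.57) and MARS1 (+1.19). Both lists also lay above all 10000 random lists. Endoplasmic reticulum chaperone and unfolded protein response genes did not follow. Their median was -0.28 (-0.50 to 0.13), below all 10000 random lists, 0 of 22 reached 2-fold, SDF2L1 (-0.80) and MANF (-0.79) were the lowest and the sensor kinase gene ERN1 (+0.83) was the highest.

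Proliferation genes were lower with ONC206. Of 57 mitosis genes, 55 were at least 2-fold lower and 0 were higher, with a median of -1.52 (-1.57 to -1.47). CDCA3 and NUF2 (-1.89), a kinetochore component, were the lowest, and CDC25B (-0.37) differed least. The 46 DNA replication genes had a median of -0.74 (-0.82 to -0.61), with 8 at least 2-fold lower, led by E2F8 (-1.41) and the thymidine kinase gene TK1 (-1.13). Replication-dependent histone genes had a median of -0.95 (-1.30 to -0.78), with 15 of 31 at least 2-fold lower. Many histone genes have near-identical copies, so single members are uncertain. All 3 lists lay below all 10000 random lists. Cholesterol synthesis genes had a median of -0.45 (-0.61 to -0.22), also below all random lists, but of 19 genes EBP (-1.01), a sterol isomerase, was the single one at 2-fold. Fatty acid synthesis genes had a median of -0.20 (-0.45 to 0.01; percentile 1.72). The p53 target list had a median of 0.19 (-0.03 to 0.30; percentile 99.95) with 0 of 23 genes at 2-fold, and its highest members were GADD45A (+0.72) and TNFRSF10B (+0.56).

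No gene of the mitochondrial lists reached 2-fold with ONC206, and the lowest were MRPS6 (-0.94) and MRPL48 (-0.82) of the mitochondrial ribosome. Complex I subunits had a median of -0.14 (-0.18 to -0.03; percentile 3.26) and 0 of 33 reached 2-fold, and subunits of complexes II to V had a median of -0.24 (-0.28 to -0.08; percentile 0.02) with 0 of 31 at 2-fold. Mitochondrial chaperones and proteases had a median of 0.01 (-0.09 to 0.09), although LONP1 (+0.72), a matrix protease, and HSPA9 (+0.39), a matrix chaperone, were at its top. Mitochondrial ribosomal proteins (median -0.10), genes of mitochondrial DNA maintenance (-0.18) and the tricarboxylic acid cycle (-0.10) lay within the central 95% of random lists. Of the 15 tricarboxylic acid cycle genes, 14 were below control by small amounts (interval of the median -0.33 to -0.06). Genes encoded in the mitochondrial genome were not analysed here.

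ONC212 gave the largest differences from control of the 3 compounds, with 503 genes at least 2-fold higher and 913 at least 2-fold lower, 11.8% of the genes kept. LINC02806 (+3.65), UNC5B (+3.54), CADM1 (+3.41), MIR3189 (+3.31), the histone methyltransferase gene SMYD3 (+3.20), CHAC1 (+3.19), the chemerin receptor CMKLR2 (+3.14), ASNS (+3.10), CBS (+2.87) and the proton pump subunit ATP6V0D2 (+2.86) were the highest. MIR3189 lies within GDF15, a stress-induced cytokine that was itself +2.42, and the array cannot separate the 2 transcripts there. The lowest were the histone genes H3C8 (-5.63) and H2BC14 (-5.32), the mitotic kinases PLK1 (-5.59) and PBK (-5.26), KIF20A (-5.40), a kinesin of cytokinesis, MKI67 (-5.28), ASPM (-5.18), DLGAP5 (-5.14), CDC20 (-5.01) and the kinetochore scaffold KNL1 (-4.83). In fold terms PLK1 was 48.1-fold and MKI67 38.9-fold lower. KIF20A was at 1.84 and H3C8 at 1.54 on the ONC212 array, under the filter level of 3.64, so such folds depend on the lower end of the array's range.

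Of the 57 mitosis genes, 56 were at least 2-fold lower with ONC212, with a median of -3.90 (-4.08 to -3.68), and 31 of them lay under the filter level on that array. CDC25B (-0.67) was the exception. DNA replication genes had a median of -1.97 (-2.15 to -1.67), with 40 of 46 at least 2-fold lower, led by the ribonucleotide reductase gene RRM2 (-4.82) and TK1 (-4.01). Histone genes had a median of -1.85 (-2.69 to -1.31), with 24 of 31 at least 2-fold lower. The p53 target list was higher, with a median of 1.05 (0.60 to 1.19) and 12 of 23 genes at 2-fold or more. GADD45A (+1.55), which restrains the cell cycle after damage, and RRM2B (+1.49) led it, and DDB2 (-0.13) was the lowest. All 4 lists lay outside all 10000 random lists.

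The stress programme was also higher with ONC212. Of 29 integrated stress response genes, 23 were at least 2-fold higher and 0 lower, with a median of 1.63 (1.22 to 2.16), above all 10000 random lists. VEGFA (+0.16) and SLC7A1 (+0.27) were the least different. Serine, one-carbon and proline synthesis genes split, with 5 of 13 at least 2-fold higher, such as ALDH1L2 (+2.54) and PSAT1 (+2.23), and 3 at least 2-fold lower, among them SHMT1 (-2.08) and PYCR3 (-1.54). Aminoacyl-tRNA synthetases had a median of 0.71 (-0.08 to 1.26) with 7 of 19 at 2-fold or more, including WARS1 (+1.87) and MARS1 (+1.50). Endoplasmic reticulum chaperone and unfolded protein response genes had a median of -0.07 (-0.69 to 0.38; percentile 29.1), with 4 of 22 at least 2-fold lower, MANF (-1.43) and SDF2L1 (-1.41) at the bottom, and ERN1 (+1.66) alone at 2-fold or more above control. NRF2 antioxidant targets had a median of 0.46 (0.32 to 0.76) with 4 of 18 at 2-fold or more, led by the cystine transporter SLC7A11 (+2.55), which is also an ATF4 target, and SRXN1 (+1.65). In the TRAIL and death receptor list (median 0.11, percentile 72.5), the receptors TNFRSF10B (+1.43) and TNFRSF10C (+1.46) were higher and TNFRSF10D (-1.0) was lower, and 3 of 12 genes were at least 2-fold higher. Among 14 BCL2 family genes (median 0.40, percentile 99.4), the pro-apoptotic BBC3 (+1.07) and PMAIP1 (+1.04) were the 2 at 2-fold or more. The FOXO target list (median 0.53, -0.42 to 1.06; percentile 99.97) held 4 genes at least 2-fold higher, among them KLF2 (+1.10) and IRS2 (+1.09), and 2 lower, PIK3IP1 (-1.18) and CITED2 (-1.04). In all, 9 FOXO targets were above control and 6 below. The intervals of the BCL2 and FOXO lists include 0.

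Lipid synthesis, matrix and central carbon genes were lower with ONC212. Of 19 cholesterol synthesis genes, 16 were at least 2-fold lower, with a median of -1.67 (-2.54 to -1.16). EBP (-3.17) and HMGCS1 (-3.00), which makes the HMG-CoA used for sterols, were the lowest and SC5D (-0.44) differed least. Fatty acid synthesis genes had a median of -0.67 (-1.70 to -0.04), with 4 of 14 at least 2-fold lower, including the desaturase FADS2 (-3.63) and the synthase FASN (-2.87). Collagen and matrix genes had a median of -0.93 (-1.43 to -0.29), with 12 of 27 at least 2-fold lower, led by the chains of type I collagen, COL1A1 (-3.01) and COL1A2 (-2.59). These 3 lists lay below all 10000 random lists. Glycolysis genes had a median of -0.40 (-0.98 to -0.23; percentile 0.1), with ALDOC (-1.91) and LDHA (-1.85) lowest and HK2 at +0.74. Tricarboxylic acid cycle genes had a median of -0.48 (-0.63 to -0.24; percentile 0.07), with IDH2 (-1.46) as the 1 gene of 15 at 2-fold. Subunits of complexes II to V had a median of -0.36 (-0.55 to -0.15; percentile 0.01), of which ATP5MC1 (-1.12) reached 2-fold, and complex I subunits one of -0.19 (-0.30 to -0.02; percentile 1.56) with 0 of 33 at 2-fold. Mitochondrial chaperones and proteases (median 0.00), mitochondrial ribosomal proteins (-0.03), mitochondrial DNA maintenance genes (-0.12) and cytosolic ribosomal proteins (-0.03) were within the central 95% of random lists.

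**Figure D2:**
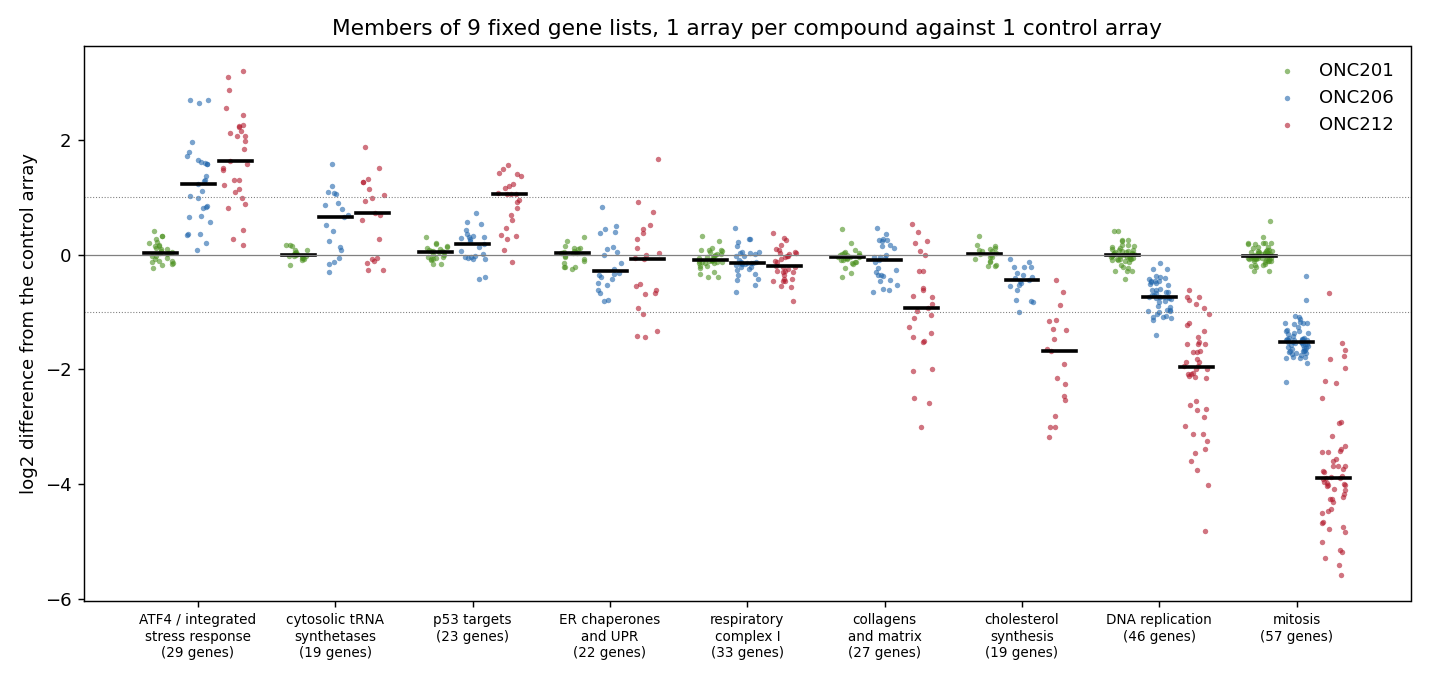
Log2 difference from the control array (y axis) for every measured member of fixed gene lists (x axis, number of genes in brackets) with ONC201, ONC206 and ONC212. Points are genes, bars are medians and dotted lines mark 2-fold; the medians of the integrated stress response list are 0.03, 1.22 and 1.63 and those of the mitosis list are -0.03, -1.52 and -3.90.

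Markers of other cell types were mostly dim. Of the neuronal list 6 genes passed the filter, with SNAP25 at -2.95 and MAP2 at +1.64 with ONC212, and 2 genes each passed for the endothelial, immune and epithelial lists. The epithelial keratin genes KRT8 and KRT14 differed from control by +0.89 and +0.64 with ONC201, +1.07 and +1.43 with ONC206, and +1.47 and +1.59 with ONC212.

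Whether ONC206 and ONC212 acted on the same genes was first read against the common control. Across genes their differences from control correlated at r = 0.768 (Spearman rho 0.698), where arrays with no effect sharing 1 control gave 0.5 in simulation (range 0.475 to 0.519 over 100 draws). The covariance was 0.236 against a simulated 0.0194. Of the genes at least 2-fold higher, 96 were shared where 5.09 would be for independent lists, and of those lower, 228 were shared where 18.9 would be. That simulated r holds for arrays of equal spread, and at the spreads of these differences the simulated covariance alone gives r = 0.0629. ONC201 correlated at r = 0.332 with ONC206 and 0.180 with ONC212, where the simulated covariance alone gives 0.212 and 0.113. The noise of the control array by itself is not known, so this excess is not read as a shared effect. The control array could not be split, so its share in these overlaps was not separated. Genes are not independent replicates, and no p-value was taken across them.

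Pairs that share no array avoid this limit, because noise of single arrays cannot make them correlate. The difference of ONC206 from control and that of ONC212 from ONC201 correlated at r = 0.676 (rho 0.571), with 80 genes at least 2-fold higher in both, 210 lower in both and 3 in opposite directions. Independent lists would share 5.26 and 17.8. The other pairing, ONC212 from control with ONC206 from ONC201, gave r = 0.689 (rho 0.580). In the first pairing UNC5B, CHAC1, CBS, LINC02806, ASNS, CADM1, C5AR1, RPS6KA2, PAPPA2 and ALDH1L2 were highest by the smaller of their differences, each of which was at least 2.11. CXADR was the lowest by the same rule, at -2.78 and -2.93, followed by CDCA3, SKA3, RTKN2 and H2BC6. The difference of ONC201 from control did not correlate with that of ONC212 from ONC206 (r = 0.00464, rho -0.000613).

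**Figure D3:**
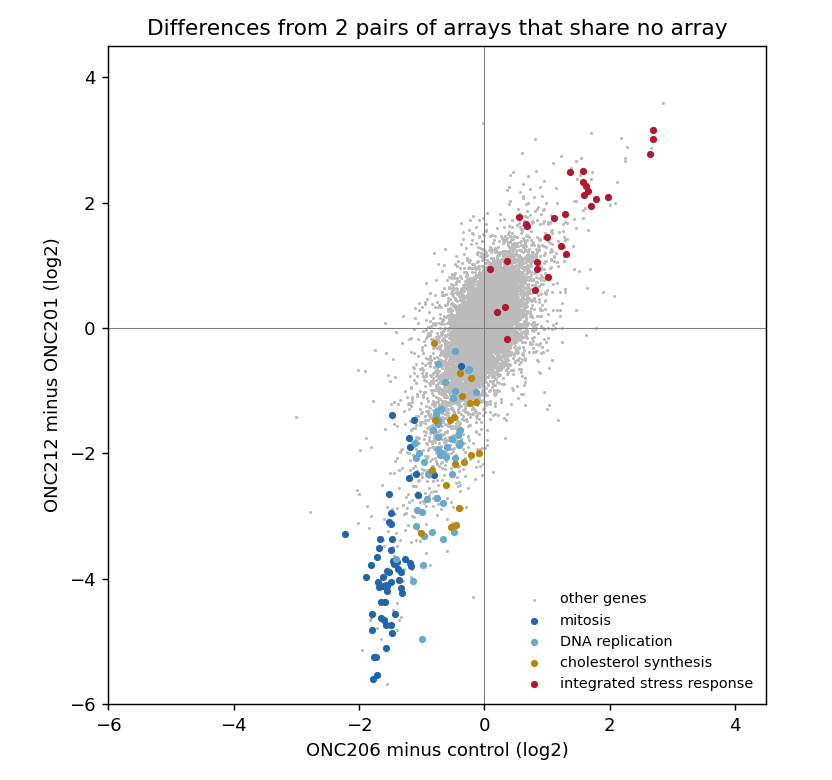
Each gene's log2 difference between ONC206 and control (x axis) and between ONC212 and ONC201 (y axis), which share no array, with members of 4 fixed lists in colour. Across all 11958 genes r was 0.676; integrated stress response genes lie at the upper right and mitosis genes at the lower left, where the ONC212 difference is larger than the ONC206 difference.

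The compounds were then compared with each other at the same dose and time. ONC206 exceeded ONC201 by at least 2-fold for 113 genes and was below it for 234. UNC5B (+2.89), CBS (+2.84), CHAC1 (+2.67), PAPPA2 (+2.45), ASNS (+2.33), C5AR1 (+2.17), RPS6KA2 (+2.10), SLC7A5 (+1.99), PCK2 (+1.98) and ALDH1L2 (+1.89) were the highest, and CXADR (-2.53), CDCA3 (-2.11), KIF20A (-1.98), NUF2 (-1.95) and SHCBP1 (-1.89) were among the lowest. Integrated stress response genes differed by a median of 1.16 (0.69 to 1.55) and mitosis genes by -1.50 (-1.54 to -1.44), close to the differences from control. ONC212 exceeded ONC201 by at least 2-fold for 520 genes and was below it for 860. UNC5B (+3.59), EIF4EBP3 (+3.27), CHAC1 (+3.17), MIR3189 (+3.11), PAPPA2 (+3.02), CBS (+3.02), SMYD3 (+3.02) and CADM1 (+2.89) were the highest and H3C8 (-5.68), KIF20A (-5.60), PLK1 (-5.53) and MKI67 (-5.25) the lowest. On the ONC201 array EIF4EBP3 (2.33), MIR3189 (2.70), PAPPA2 (3.58) and CADM1 (2.97) lay under the filter level, so their ranks depend on the lower end of its range. The medians of ONC212 against ONC201 were 1.75 (1.07 to 2.12) for the integrated stress response, -3.89 (-4.11 to -3.72) for mitosis and -1.99 (-2.50 to -1.18) for cholesterol synthesis. Without replicates no interval of the compounds' difference over cultures can be given.

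ONC212 and ONC206 differed most in proliferation, sterol and matrix genes. ONC212 was at least 2-fold higher for 170 genes and at least 2-fold lower for 466. SMYD3 (+2.40), the tight junction gene CLDN1 (+1.98), EIF4EBP3 (+1.97), RPLP0P2 (+1.97), BAMBI (+1.96), ANKRD22 (+1.77), TAS2R4 (+1.72), ZNF474 (+1.67), ZBED3-AS1 (+1.66) and ZNF181 (+1.66) were the highest. On the ONC206 array EIF4EBP3 (3.62), BAMBI (2.20), ANKRD22 (2.79), TAS2R4 (2.05), ZNF474 (2.76) and ZBED3-AS1 (2.25) lay under the filter level. Their differences and ranks therefore depend on the lower end of the array's range. CLDN1, ANKRD22 and ZBED3-AS1 overlap another gene on the array in the annotation. H3C8 (-4.08), PLK1 (-3.88), RRM2 (-3.83), H2BC14 (-3.67), KIF20A (-3.62), the carboxypeptidase gene CPA4 (-3.62), DLGAP5 (-3.57), MKI67 (-3.55), ESCO2 (-3.44) and ASPM (-3.43) were the lowest. The mitosis list was lower by a median of -2.41 (-2.63 to -2.10), with 51 of 57 genes at 2-fold, DNA replication by -1.23 (-1.65 to -0.95), cholesterol synthesis by -1.59 (-1.93 to -0.82) and collagens and matrix by -0.79 (-1.22 to -0.55). The p53 target list was higher by 0.77 (0.59 to 0.87), with MDM2 (+1.27), the ubiquitin ligase of p53, and RRM2B (+1.2) at its top. The integrated stress response list differed less, by 0.41 (0.18 to 0.68), with 3 of 29 genes at 2-fold, among them ATF3 (+1.27) and PPP1R15A (+1.05). Aminoacyl-tRNA synthetases differed by 0.13 (0.01 to 0.24) with 0 of 19 genes at 2-fold. Under the stricter filter on dim genes, 75 genes in place of 170 were higher.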

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

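The tests on the ratio of responses, the array ceiling, dim features, the sign of the ONC201 genes, the trend with level and shared list members were chosen after the result was seen.

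Probe sets without a gene name were left out of the comparisons, and some of them also differed from control. Of 554 that passed the filter, 3 were at least 2-fold higher and 2 lower with ONC201, 6 higher and 8 lower with ONC206, and 25 higher and 35 lower with ONC212.

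ONC206 reached a larger part of the ONC212 response in stress genes than in mitosis genes. With no array shared, the ONC206 over ONC212 ratio of list medians was 0.709 for the integrated stress response (bootstrap interval over genes 0.475 to 0.836) and 0.385 for mitosis (0.368 to 0.403). The 13 stress genes under the 95th percentile of the ONC212 array gave 0.526 (0.314 to 0.893). This wide interval holds both the mitosis ratio and the 0.709 of the full list. It cannot tell whether the contrast rests on the bright members, and compression of bright probe sets may account for it. No member sat at a limit shared by all probe sets, since the highest read 10.6 with ONC212 where the array reached 12.1 and 75 genes lay above it. The p53 targets gave 0.0894 (-0.00619 to 0.299), or 0.219 (-0.0378 to 0.337) in the other pairing. Mitosis gave 0.390 (0.369 to 0.408) in that other pairing, so p53 targets lay below mitosis in both. DNA replication gave 0.356 (0.308 to 0.413), or 0.376 (0.319 to 0.418) in the other pairing, which overlaps p53 targets. Histone genes gave 0.557 (0.419 to 0.652), or 0.449 (0.370 to 0.691). On the ONC212 array 31 of 57 mitosis, 11 of 46 replication and 13 of 31 histone genes lay under the filter level. A floor there may raise their ratios. It does not bear on p53 targets, since 0 of 23 lay under the filter level on that array. The stress response gave 0.697 (0.509 to 0.893) in the other pairing, so its interval lay above that of p53 targets in both. In the first pairing this also held, narrowly, for the 13 dimmer stress genes. These values argue against 1 factor for these 2 lists on these arrays. With 1 culture per group they do not extend to the compounds.

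The 51 genes at least 2-fold apart between ONC201 and control had a median level of 3.50, and 47 of them lay below the 25th percentile of all genes kept, 4.78. The spread between these arrays was 0.282 on average in the 5 dimmest level bins and 0.150 in the other 15. Noise of dim features may therefore account for most of them. Of the 51 genes, 23 had the same sign between ONC212 and ONC206, or 45.1% (exact 95% interval 31.1 to 59.7, with genes taken as independent). Noise of dim genes alone would give a share near 50%, which could hide a response, so a weaker form of the ONC206 and ONC212 responses stays open.

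The hypoxia list was higher with ONC201 and lower with ONC212 (median -0.37), where 7 of 22 genes were at least 2-fold lower, led by STC1 (-2.89) and PDK1 (-1.85), and 2 were at least 2-fold higher, DDIT4 (+1.30) and MXI1 (+1.02). The medians of all genes in 20 level bins ran from -0.0531 to 0.0291 with ONC201 and from -0.0537 to 0.106 with ONC212, outside the intervals of the list medians, so a trend with expression level does not account for it. Without the members shared with the stress response list the medians were 0.303 with ONC201 and -0.506 with ONC212, each outside random lists. Among causes left open, oxygen supply or cell density that differed between the dishes may account for either shift, and with 1 culture per group this cannot be told apart from the compounds.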

How the results depend on the processing

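No list outside the central 95% of random lists changed sign under any alternative, and no result was counted as moved under cyclic loess normalization. A list counted as moved when its new value left the 95% interval over its genes, which is wide for some lists. A gene count was moved when it changed by more than 1.5-fold, and a correlation when it left its bootstrap interval over genes. The percentiles among random lists were not recomputed under the alternatives. Of 198 list medians, 24 had a mean of opposite sign, all of them inside the central 95%. Counts depended on the threshold by construction. At 1.5-fold the genes higher and lower were 136 and 155 for ONC201, 547 and 827 for ONC206 and 1530 and 1767 for ONC212 against control, 534 and 784 for ONC206 and 1608 and 1690 for ONC212 against ONC201, and 831 and 1139 for ONC212 against ONC206. ONC201 against control was the least stable. It had 75 genes higher and 47 lower with no filter on dim genes, and 1 and 3 with the stricter filter, which turns the balance of 30 higher and 21 lower. The stricter filter also gave 72 genes higher for ONC206 against control, 68 for ONC206 against ONC201 and 75 for ONC212 against ONC206, since fewer dim genes are counted. Centring of the arrays moved the median of the mitosis list with ONC206 to -1.44, of the tricarboxylic acid cycle list with ONC206 to -0.018, and of mitochondrial ribosomal proteins to -0.026 with ONC201 and -0.024 with ONC206. The mean of the histone list with ONC201 was -0.021 in place of a median of -0.081. The cause of the shifts in correlation was not tested. Between the differences that share no array they were 0.529 and 0.532 with no filter, 0.748 and 0.755 with the stricter filter, and 0.630 and 0.641 without the 100 most variable genes. Without the cell cycle, histone and integrated stress response lists, a setting chosen after seeing the data, they were 0.633 and 0.643. Against the shared control, no filter gave 0.391 for ONC201 and ONC206, 0.243 for ONC201 and ONC212 and 0.693 for ONC206 and ONC212. The stricter filter gave 0.267, 0.139 and 0.804 in that order, and removal of the 100 most variable genes gave 0.740 for the last pair. No paired analysis was possible because each group had 1 array. What limits all results is the lack of replicates and, for genes under the filter level, a signal near the lower end of the array.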

Other observations

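Other gene groups held single genes far from control. In the inflammatory list IL1A, an alarmin cytokine, was +1.54 with ONC206 and +2.80 with ONC212, and CXCL5 was +1.72 with ONC212, while the chemokine genes CCL2 (-3.03) and CXCL1 (-1.36) were lower with ONC212. Of 24 genes in that list 7 were at least 2-fold higher and 3 lower with ONC212. CXCL1 (-1.18) and CCL2 (-0.89) were also the lowest of the list with ONC201. Interferon-stimulated genes went both ways with ONC212, with OAS3 at -1.96 and MX2 at +1.19 and a median of 0.07. Autophagy and lysosome genes had medians of 0.17 with ONC206 and 0.25 with ONC212 (percentiles 99.9 and 99.2), with MAP1LC3B (+1.19) and MAP1LC3A (+1.13) highest under ONC212. Immediate early genes had a median of -0.31 with ONC212 (-0.72 to 0.02; percentile 0.47), led by NR4A3 (-1.37) and SPRY2 (-1.20). Cytosolic heat shock proteins had a median of -0.30 (percentile 3.13) and 0 of 14 genes at 2-fold.

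Among glioma and neural stem cell genes, CHI3L1, a secreted glycoprotein of mesenchymal glioma, was -2.98 and the glutamate transporter SLC1A3 -1.54 with ONC212, and the lineage factor OLIG2 was +1.37, with 10 genes measured and a median of -0.38. The matrix metalloproteinase list had a median of -0.16 with ONC212, with ADAMTS5 at +2.39 and the urokinase gene PLAU at -1.62. In the TGF-beta and YAP list CCN2 was -2.32 and ACTA2 +1.22 with ONC212, with a median of -0.19 but a mean of 0.01. Of the dopamine list 4 genes passed the filter, and DRD4 was +1.2 with ONC201, +0.96 with ONC206 and +0.18 with ONC212. With ONC201 DRD5 was -0.56, SLC6A3 +0.13 and MAOA +0.23, so the 4 genes went both ways. DRD4 is 1 of the 51 genes at least 2-fold apart with ONC201, most of which were dim.

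Bounds for both tests here were written before their outcomes were known, but the zinc finger group was picked after some of its members were seen. Zinc finger genes appeared among the highest of ONC212 against ONC206, so all 291 measured genes named ZNF were taken as a group. Their median with ONC212 against control was 0.191, above the limit of 0.0863 from 1000 random lists, with 15 genes at least 2-fold higher and 9 lower, so a small shared shift may exist. The comparison that drew attention to these genes uses the same ONC212 array, so the test is not independent of the pick. Transcripts that host small nucleolar RNAs can be higher when translation is limited, so 19 such genes were tested. In ONC212 against control, which was not part of the test, single members went both ways. GAS5 was +1.57 and ZFAS1 +0.84, while SNHG12 was -0.80 and SNHG3 -0.64. The medians of the 19 genes were 0.0923 for ONC206 against control and 0.207 for ONC212 against ONC201. Both lay inside the random limits, with upper limits of 0.140 and 0.299. That leaves the idea undecided.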
